A study of Mus musculus with 12 samples.

How the data were processed

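Hippocampal RNA of 12 mice was measured on 24 one-colour oligonucleotide arrays, 2 for each animal. Per the labels, RNA was extracted with Trizol, amplified with the Ovation kit and labelled with Cy3 by the array maker, NimbleGen. The deposited array files hold a linear intensity for each feature together with its standard error, and the authors computed it with RMA, per the submitters' processing notes, which give no version. RMA is by definition a background correction, a quantile normalization and a summary of the probes of a feature. Whether RMA was run on all 24 arrays together is not given in the sources used here. Each array file has 44190 entries, of which 44170 are gene features (44155 of them made of 3 probes) and 20 are control entries, which were left out. The table of the whole series holds log2 values that the authors made from the same arrays. For 11 animals it equals the log2 of the mean of the 2 linear values within 5e-09, and for MSUS animal 29 it equals the first array alone within 5e-09, so the authors' table leaves out the second array of that animal. The files and labels do not say why.

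Feature positions are those of the mouse build mm9, per the file headers of the array design. Gene names come from the Entrez identifiers in the files, matched to a RefSeq table of assembly GRCm38.p6 that was used for names only. Of the 44170 features, 39057 matched, 2829 kept the name in the file and 2284 had no gene name. The named features stand for 24171 genes, of which 10215 have more than 1 feature. The level of 5000 random probes on each array served as background, and 27231 features (61.7%) had a mean more than 2-fold above it.

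The intensities were taken to the log2 scale with no further normalization and no filter, and the 2 arrays of an animal were averaged, so that each animal counted once. The 6 MSUS and 6 Control animals were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with no covariate. Differences are MSUS minus Control, and adjusted p-values are Benjamini-Hochberg values over all features with a threshold of 0.05, two-sided. Intervals are at the 95% level. The animal numbers in the labels differ between the groups, so nothing pairs the animals. The labels do not give the litters, and animals of one father would share more than the model assumes.

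A total of 31 gene lists and 18 single genes were fixed before the data were examined. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, on 1 feature per gene (the one with the highest mean over the 12 animals), against the other genes, with adjustment over the 31 lists. The same lists were tested with an estimated correlation and with fry, which asks whether the members of a list move one way on balance. An exact two-sided permutation test of the list score, the mean of the members' centred log2 values in an animal, over all 924 assignments of the 12 animals was added after seeing the data. The single genes were adjusted over the list alone and over all features. The choice of 1 of the 18 was not independent of earlier knowledge of this study. Egr1 and Htr1a were on the list and had no feature under those names. The rule for named genes, also fixed in advance, takes up to 12 features per direction past the threshold. Where fewer than 12 pass, the features with the smallest p fill up to 6 per direction. It adds the fixed genes, the 4 members with the smallest p of each list past the camera threshold and up to 2 of each other list.

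The arrays lay on 2 slides, each with 12 arrays and both groups. MSUS animal 10 had both arrays on the first slide and Control animal 15 both on the second. The outlying array of MSUS animal 29 lay on the second slide, where it was the only array of that animal. Alternatives fixed in advance were the slide as a block with the animal as a random block (duplicateCorrelation, statmod 1.5.0), each slide alone, animals with arrays on both slides, the authors' table of values, a further quantile normalization, centring each array on its median, leaving out the dimmest 25% or 50% of features, a trended and robust variance, array weights, an adjusted p threshold of 0.1, 1 feature or the mean of all features per gene, and leaving out each animal in turn. Fits without the outlying array of MSUS animal 29 were added after seeing the data.

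The procedure was tested on simulated data with the spread of these 12 animals for the comparison of MSUS with Control over 44170 features. A true difference of 0.25 on the log2 scale was called in 31.8% of 500 changed features, one of 0.5 in 76.8%, one of 1 in 96.2% and one of 2 in 99.8%, and 4.15% of calls were false. The simulated features varied independently of each other. All sizes were planted in the same runs, which eases the adjusted threshold for the smaller ones. These shares therefore do not give the power of the real comparison. Simulated lists of 22 unchanged genes among 3000 were counted as called at an unadjusted p under 0.05, each list alone. Camera at the preset correlation called 4% with independent members, 13% at a true correlation of 0.05, 30% at 0.2 and 49% at 0.5. With the correlation estimated, 2% to 5% were called. Camera calls in the results use p-values adjusted over all lists, so these shares are not the false-call rates of those calls. The number of animals, 6 in each group, limits the precision.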

Results

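Gene expression was compared in the hippocampus of F2 C57BL/6J mice whose fathers had or had not been stressed early in life. MSUS stands for maternal separation combined with unpredictable stress, applied to the fathers in their early postnatal life. The fathers were bred to untreated females. The 6 MSUS animals are offspring of stressed fathers and the 6 Control animals are offspring of fathers with control handling. All 12 had swum for 6 min in water at 18 °C and were killed 2 weeks later, the resting state of the study, which also asked about memory and synaptic plasticity in such offspring. The sex of the animals is not stated in the labels.

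Each animal was measured on 2 arrays. Median log2 intensity was between 7.24 and 7.31 on 23 arrays and 7.54 on the second array of MSUS animal 29. The random-probe signal was between 39.7 and 41.5 on those 23 arrays and 46.6 on that array. After subtraction of the feature means, all 24 arrays correlated best with the other array of the same animal. The correlation within an animal was between 0.529 and 0.790 for 11 animals and 0.217 for MSUS animal 29, while no pair of arrays from different animals exceeded 0.203 (outlying array left out). The consensus correlation between arrays of one animal was 0.543 over all arrays and 0.692 without the outlying array. Between the slides, 1983 features differed (limma, slide as a block, without the outlying array).

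**Figure D1:**
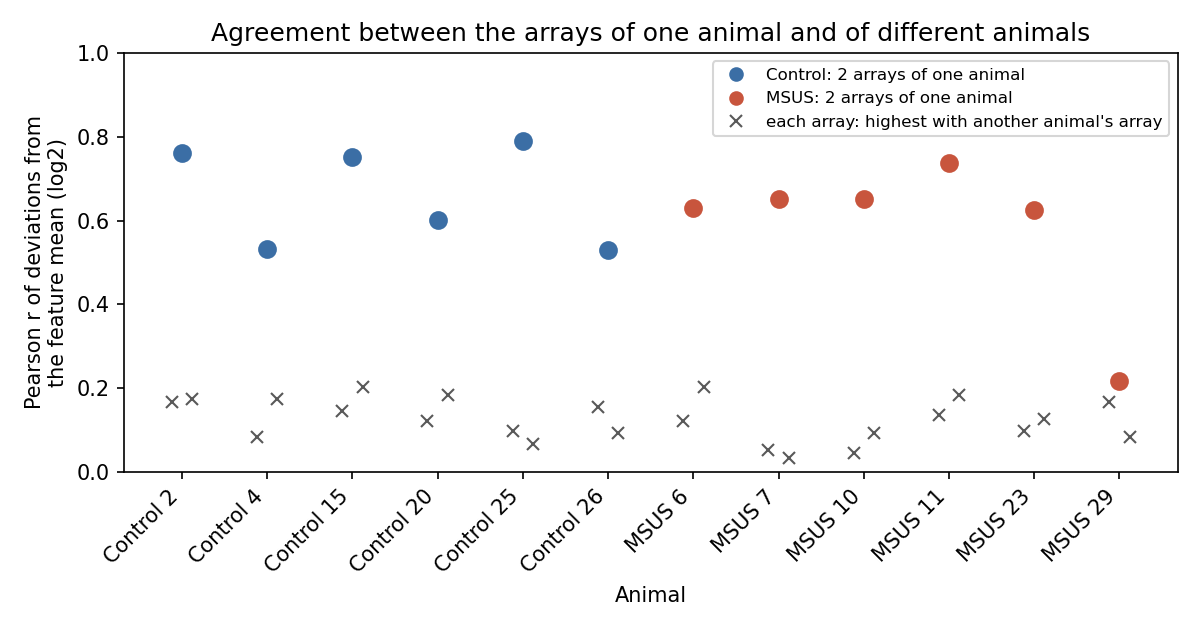
Pearson correlation of log2 deviations from the feature mean (y axis) for each of the 12 animals (x axis). Filled points are the 2 arrays of one animal (Control blue, MSUS red), between 0.529 and 0.790 except 0.217 in MSUS 29, and crosses give, for each array, its highest correlation with an array of another animal.

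Offspring of stressed fathers had no transcript that passed the threshold against offspring of control fathers. limma called 0 of 44170 features at an adjusted p under 0.05, and the smallest adjusted p rounded to 1.00. At an unadjusted p under 0.05 there were 1572 features, where 2208 would be expected with no difference at all. Of these, 1237 were higher and 335 lower in MSUS animals. Without the outlying array the split was 619 higher and 674 lower of 1293, with values centred on each array's median it was 823 and 519, and with quantile normalization repeated it was 847 and 545. The 95% interval of the difference lay within ± 0.5 on the log2 scale for 42106 features (95.3%), and the interval reached a median of 0.148 to each side. The groups did not overlap at 56 features, 0.127% of all, where chance gives 0.216%. On the first slide alone 0 features passed with 1538 at an unadjusted p under 0.05, on the second 0 with 1449, and with the slide as a block 0 with 1714.

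The 6 features with the smallest p among those higher in MSUS animals did not pass (adjusted p = 1.00 each, limma). Spats1, a gene named for its association with spermatogenesis (mm9 chromosome 17, 45586041 to 45611847), measured 7.93 ± 0.078 in MSUS and 7.66 ± 0.085 in Control animals (log2 mean ± SD, n = 6 each), a difference of 0.27 with an interval of 0.16 to 0.38. Pilra, an inhibitory receptor of myeloid cells, differed by 0.34 (0.18 to 0.50), with 1 of its 2 features going the other way. Ms4a6b, a membrane protein of immune cells, differed by 0.20 (0.10 to 0.29) and Chp2, a calcineurin B homologue, by 0.26 (0.145 to 0.38; chromosome 7, 129363009 to 129366053). The RIKEN transcripts 4833415N18Rik and 2010010A06Rik differed by 0.39 and 0.28. All 6 MSUS animals lay above the Control mean at each of the 6 features. Pilra, 4833415N18Rik and Chp2 averaged 1.02, 1.13 and 1.18 log2 units above the random probes, just over 2-fold, and the others 1.57 to 2.45.

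Among features lower in MSUS animals, Tex26, a testis-expressed gene (mm9 chromosome 5, 150242280 to 150273195), had the smallest p and did not pass either. It measured 6.63 ± 0.18 in MSUS and 7.13 ± 0.19 in Control animals (SD, n = 6 each), a difference of -0.49 with an interval of -0.71 to -0.28. With the outlying array left out and the slide as a block, Tex26 was the single feature that passed (-0.50 ± 0.071 (SE), adjusted p = 0.0155). Nlrp4g, of the NLRP family, differed by -0.56 (-0.86 to -0.27), Nsun6, an RNA methyltransferase, by -0.36 (-0.53 to -0.19), Adam32, of the ADAM protease family, by -0.30 (-0.45 to -0.14), and Slco5a1, of the organic anion transporter family, by -0.22 (-0.33 to -0.11). The adjusted p of these was 1.00 each. Of the other features of Nsun6, 4 went the other way, as did 1 of Nlrp4g, 1 of Slco5a1 and 2 of Adam32. Nsun6, Nlrp4g and Adam32 averaged 0.50, 0.70 and 0.99 log2 units above the random probes, under 2-fold, and Slco5a1 1.06.

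The genes fixed in advance for plasticity, the stress axis, DNA methylation and glia were measured at levels that did not separate the groups. Of 16 measured, 0 passed adjusted over the list alone (smallest adjusted p = 0.867) and 0 over all features, and 0 had an unadjusted p under 0.05 in limma. Grin2b, an NMDA receptor subunit (mm9 chromosome 6, 135993908 to 136121907), had the largest difference, 11.83 ± 0.14 in MSUS and 12.01 ± 0.20 in Control animals (SD, n = 6 each), -0.18 with an interval of -0.38 to 0.024. Bdnf, the neurotrophin (chromosome 2, 109563536 to 109564667), differed by 0.10 (-0.032 to 0.24), Gria1, an AMPA receptor subunit, by -0.0030 (-0.088 to 0.082) and Camk2a, the synaptic calcium kinase, by -0.039 (-0.19 to 0.12). The corticosteroid receptors Nr3c1 and Nr3c2 differed by -0.070 (-0.27 to 0.13) and 0.058 (-0.065 to 0.18), their co-chaperone Fkbp5 by 0.047 (-0.095 to 0.19) and the receptor of corticotropin-releasing hormone, Crhr1, by 0.056 (-0.13 to 0.24). The DNA methyltransferases Dnmt1 and Dnmt3a differed by 0.043 (-0.13 to 0.22) and -0.072 (-0.29 to 0.14). Gfap, of astrocytes, differed by -0.012 (-0.12 to 0.097) and Mbp, of myelin, by -0.061 (-0.17 to 0.047). The activity-regulated genes Arc and Fos had the widest intervals, 0.086 (-0.44 to 0.61) and -0.046 (-0.95 to 0.86), the only 2 of the 16 that reach beyond ± 0.5. Camk2a, Crhr1, Dnmt1, Gfap and Mbp each have 1 further feature that went the other way.

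**Figure D2:**
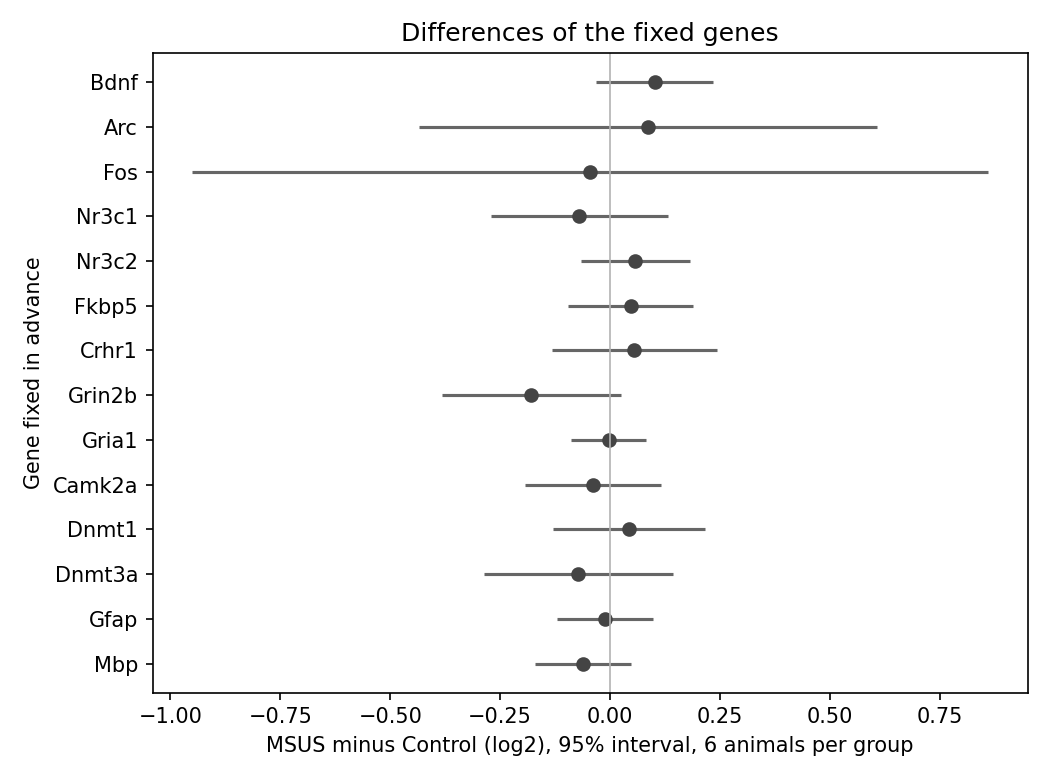
Difference between MSUS and Control animals on the log2 scale (x axis) for 14 of the 16 measured genes fixed in advance (y axis). Points are differences of group means of 6 animals and lines are 95% intervals from limma, all of which include 0, and those of Fos and Arc are the widest.

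Of the synaptic lists, 3 passed camera on the lower side with the preset correlation alone, with means of a few hundredths of a log2 unit, and single members did not pass. Of the 31 gene lists, 9 passed camera with the preset correlation, 3 higher and 6 lower, and 0 of these calls held with an estimated correlation (smallest adjusted p = 0.494). The postsynaptic scaffold list (26 genes, 18 lower) had a mean difference of -0.039 ± 0.027 (SE over animals; adjusted p = 0.0212 in camera). With an estimated correlation the adjusted p = 0.497, and without the outlying array the camera call ended (mean -0.034, adjusted p = 0.0559). Its members with the smallest p were the synaptic adhesion protein Nlgn1 (-0.13 ± 0.073 SE), the scaffold proteins Dlg2 (0.048 ± 0.039) and Homer1 (0.055 ± 0.046), and gephyrin, Gphn (-0.46 ± 0.43), with 2 of the 4 features of Dlg2 and 1 of the 2 of Homer1 going the other way. Gphn read 6.40 on the outlying array, 12.04 on its pair and between 11.88 and 12.26 on the arrays of the other animals. The presynaptic release list (38 genes, 24 lower) had a mean of -0.028 ± 0.020 (adjusted p = 0.0170, and adjusted p = 0.494 with an estimated correlation) and a median of -0.0072. Without the outlying array the presynaptic mean was -0.024 and still passed camera with the preset correlation (adjusted p = 0.0356). It did not pass with an estimated correlation (adjusted p = 0.53). The vesicle protein Sv2a, chosen here after its value was seen, differed by -0.66 ± 0.555, and it read 5.71 on the outlying array and 13.36 on its pair. Pclo, of the active zone, differed by -0.10 ± 0.054, Rims1 by -0.044 ± 0.035, the vesicle protein Sv2c by 0.19 ± 0.13 and the calcium sensor Syt7 by 0.082 ± 0.062, with 1 of the 4 features of Sv2c going the other way. The GABA system list (21 genes, 13 lower) had a mean of -0.023 ± 0.033 (adjusted p = 0.0238, and adjusted p = 0.526 with an estimated correlation). It was -0.040 without the outlying array (adjusted p = 0.0235) and -0.043 to -0.0036 with 1 animal left out. Its receptor subunit Gabrb2 (-0.14 ± 0.10) and the GABA-producing enzyme Gad2 (-0.12 ± 0.084) were on the lower side and Gabrg1 (0.12 ± 0.048) on the higher side, with 1 of the 2 features of Gabrb2 and 1 of the 3 of Gabrg1 going the other way. With the slide as a block the means of these 3 lists were -0.041, -0.029 and -0.017. On the first slide they were -0.033, -0.025 and -0.038, and on the second -0.035, -0.027 and 0.0034, where the GABA list has the other sign. The outlying array was the only array of MSUS animal 29 on the second slide. The median difference over all features on the second slide was 0.044, so the GABA mean lay below it. None passed on the first slide alone (adjusted p = 0.149, 0.123 and 0.0912) or on the second (adjusted p = 0.155, 0.134 and 0.158). None of the 85 members passed adjusted over the list alone or over all features.

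The lists of glutamate receptors (22 genes, mean -0.0085 ± 0.046, adjusted p = 0.117) and of plasticity kinases and phosphatases (43 genes, mean -0.013 ± 0.019, adjusted p = 0.102) did not pass camera. The glutamate receptor mean was -0.029 without the outlying array and -0.042 to 0.012 with 1 animal left out, and each of these 2 lists passed in 3 of those 12 cases. With an estimated correlation over all 12 animals their adjusted p = 0.866 and 0.859. The median of the kinase list was -0.00034. Camkk2, an activator of the calcium kinases, differed by 0.25 ± 0.12 (SE) among the kinases, with 1 of its 7 features going the other way. The interneuron markers (24 genes) had a mean of 0.0092 ± 0.041 (adjusted p = 0.466). The monoamine and acetylcholine receptors (32 genes) had a mean of -0.020 ± 0.018 (adjusted p = 0.243) and a median of the other sign, 0.012; the serotonin receptor Htr5b differed by 0.21 ± 0.092 and the nicotinic subunit Chrnb2 by -0.14 ± 0.062. Neurotrophins and growth factors (28 genes) had a mean of 0.022 ± 0.028 (adjusted p = 0.884).

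Lists of respiration, translation and protein folding genes passed camera on the higher side with the preset correlation alone. In the oxidative phosphorylation list, the subunits of the mitochondrial respiratory chain and ATP synthase, 62 of 68 genes were on the higher side, with a mean of 0.035 ± 0.024 (SE over animals; camera adjusted p = 0.0117, and adjusted p = 0.866 with an estimated correlation). Atp5j differed by 0.14 ± 0.051, Ndufa1 by 0.085 ± 0.049, Ndufa7 by 0.075 ± 0.045 and Ndufb7 by 0.073 ± 0.041. Of 75 cytosolic ribosomal protein genes 70 were on the higher side, with a mean of 0.029 ± 0.021 (adjusted p = 0.0207, and adjusted p = 0.866 with an estimated correlation). Rps27 differed by 0.099 ± 0.053, Rpl26 by 0.076 ± 0.037, Rpl34 by 0.069 ± 0.040 and Rpl35 by 0.057 ± 0.031. The list of protein folding and heat shock genes had 25 of 30 on the higher side and a mean of 0.059 ± 0.019 (adjusted p = 0.0175, and adjusted p = 0.494 with an estimated correlation). Sdf2l1, of an ER chaperone complex, differed by 0.29 ± 0.080 (adjusted p = 0.0911 over the list alone), Creld2, an ER stress-induced gene, by 0.17 ± 0.082, Xbp1, the transcription factor of the unfolded protein response, by 0.12 ± 0.045 and the chaperone calreticulin, Calr, by 0.099 ± 0.042. The folding score was above the Control mean in 5 of 6 MSUS animals (exact permutation p = 0.0152, adjusted p = 0.470 over the 31 lists). Without the outlying array the means of the 3 lists were 0.029, 0.026 and 0.045. All 3 then passed camera with the preset correlation (adjusted p = 0.000715, 0.000688 and 0.0188). None did with an estimated correlation (adjusted p = 0.731, 0.731 and 0.53). With the slide as a block the means of the 3 lists were 0.038, 0.031 and 0.061. They were 0.046, 0.037 and 0.054 on the first slide, where all 3 passed (adjusted p = 3.57e-06, 6.14e-05 and 0.0297), and 0.034, 0.030 and 0.069 on the second, where none did (adjusted p = 0.492, 0.588 and 0.134). With 1 animal left out, the respiration list passed in 9 of 12 cases, the ribosomal list in 6 and the folding list in 8. Their means then ran from 0.019 to 0.049, from 0.018 to 0.042 and from 0.049 to 0.071. None of their members passed adjusted over the list alone or over all features.

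**Figure D3:**
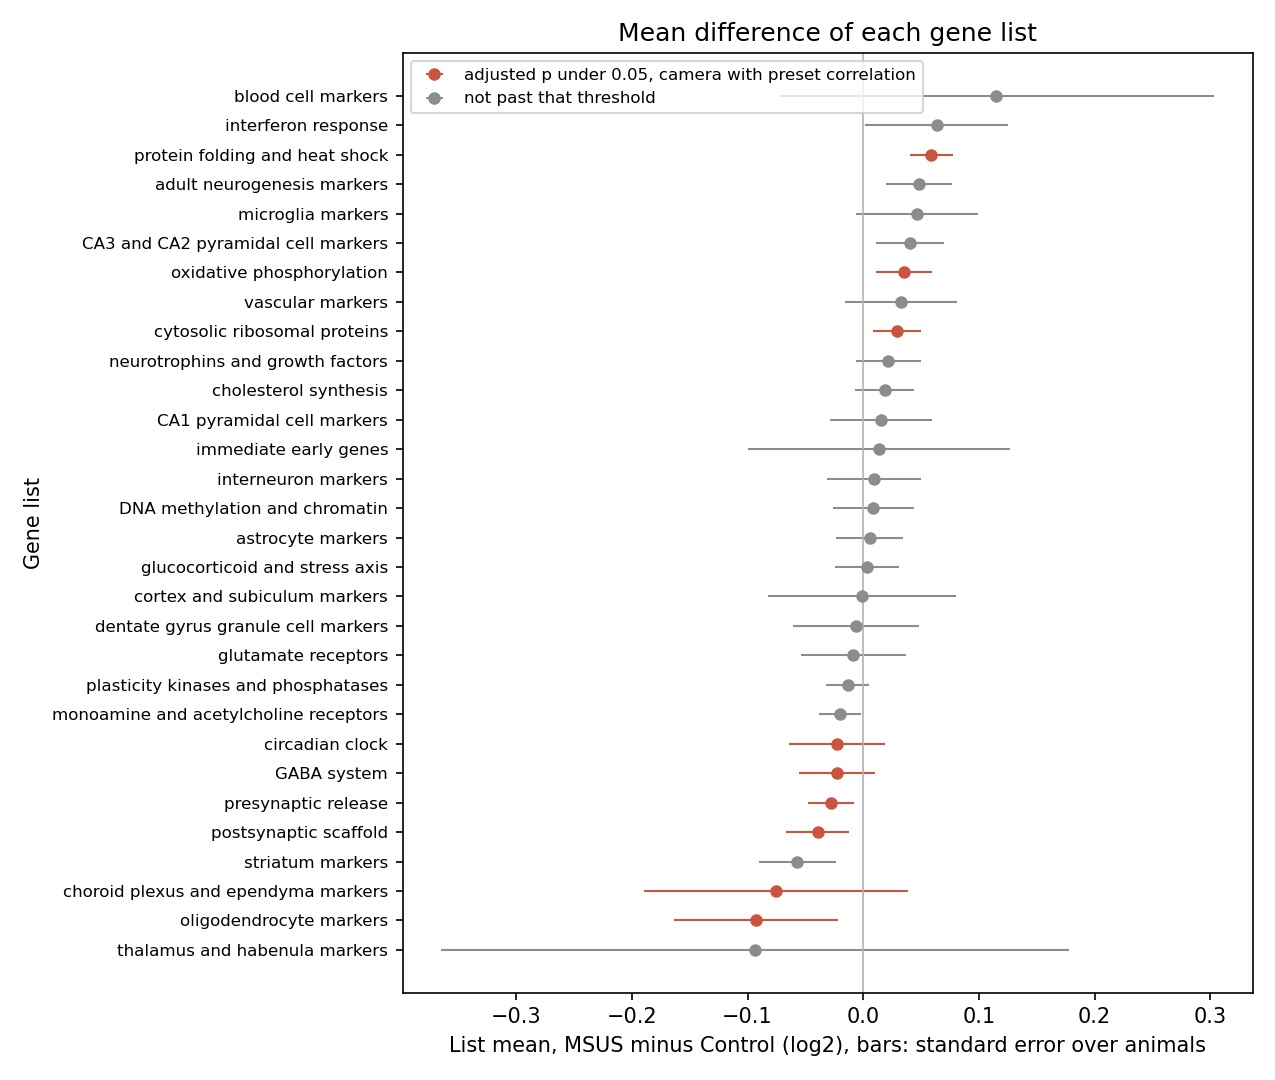
Mean log2 difference between MSUS and Control animals (x axis) for 30 gene lists (y axis), with bars for the standard error over animals. The 9 lists past camera's threshold with the preset correlation are in red; 0 passed with an estimated correlation.

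Markers of myelin-forming cells had the smallest p in camera with the preset correlation, and other lists had it in the other tests. Of 22 oligodendrocyte markers, 19 were lower in MSUS animals, with a mean of -0.093 ± 0.071 (SE over animals; camera adjusted p = 8.23e-08). The estimated correlation between its members was 0.49, with which the adjusted p = 0.494. Enpp2, a lysophospholipase, differed by -0.14 ± 0.061 (1 of its 3 features went the other way), the myelin protein genes Mobp and Opalin by -0.11 ± 0.068 and -0.16 ± 0.097, and Aspa, aspartoacylase, by -0.415 ± 0.25, the last lowered by the outlying array (7.26 against 9.99 on its pair). The score was below the Control mean in 4 of 6 MSUS animals and ran from -0.21 to 0.10 in them against -0.12 to 0.18 in Control animals (exact permutation p = 0.216). Its mean was -0.090 with the slide as a block, -0.063 on the first slide (adjusted p = 0.00552), -0.083 on the second (adjusted p = 9.61e-07) and -0.098 without the outlying array. Astrocyte markers (20 genes) had a mean of 0.0056 ± 0.029 (adjusted p = 0.466), microglia markers (20 genes) one of 0.046 ± 0.053 (adjusted p = 0.466, and 0.060 with adjusted p = 0.0428 on the first slide alone) and vascular markers (24 genes) one of 0.033 ± 0.048 (adjusted p = 0.589). With an estimated correlation over all 12 animals the microglia list had an adjusted p = 0.866. Without the outlying array the astrocyte, microglia and vascular means were -0.0071, 0.022 and 0.011. With 1 animal left out the microglia mean was 0.018 to 0.075 and the vascular mean 0.0068 to 0.060. Among the members of these lists, the microglial receptor P2ry13 differed by 0.28 ± 0.10 (SE) and the endothelial genes Cldn5 and Esam by 0.19 ± 0.084 and 0.14 ± 0.062.

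Markers of tissue next to the hippocampus varied between animals of both groups. The choroid plexus and ependyma list, 16 of 22 lower, had a mean of -0.075 ± 0.11 (SE over animals; camera adjusted p = 0.00363, and adjusted p = 0.633 with an estimated correlation). It was -0.070 with the slide as a block, -0.11 on the first slide (adjusted p = 0.0111) and 0.0023 on the second (adjusted p = 0.134). With 1 animal left out it was -0.14 to -0.010, past camera in 10 of 12 cases, and without the outlying array it was -0.091 (adjusted p = 0.0119). Ccdc153, of ependymal cilia, differed by -0.54 ± 0.36, the cilia regulator Foxj1 by -0.21 ± 0.13 and the prolactin receptor Prlr by -0.15 ± 0.096 (2 of its 7 features went the other way), and Enpp2 is on this list too. Thalamus and habenula markers (16 genes) had a mean of -0.093 ± 0.27 (adjusted p = 0.136), with scores from -0.41 to 0.92 in Control animals and -0.37 to 0.66 in MSUS animals. With 1 animal left out the thalamus and habenula mean was -0.24 to 0.080, past camera in 3 of 12 cases. With an estimated correlation over all 12 animals its adjusted p = 0.866. Striatum markers (15 genes, 8 lower) had a mean of -0.057 ± 0.033 (camera adjusted p = 0.0865) and a median of -0.0049. Without the outlying array the striatum mean was -0.039 (camera adjusted p = 0.247). Cortex and subiculum markers (16 genes) had a mean of -0.00074 ± 0.081 (adjusted p = 0.237, median 0.0017) and blood cell markers (12 genes) one of 0.12 ± 0.19 (adjusted p = 0.775).

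**Figure D4:**
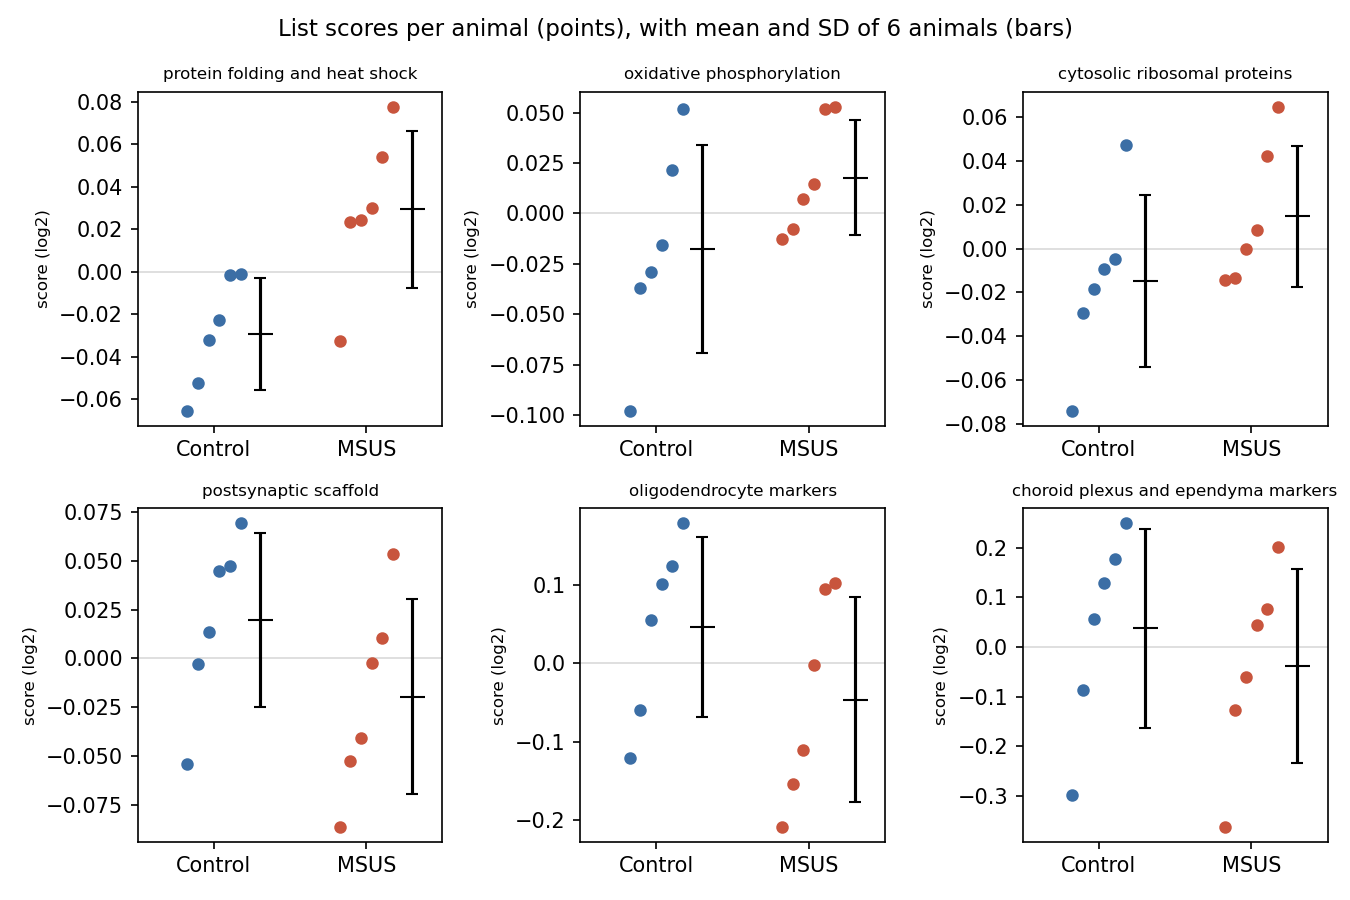
Score of each animal (points, log2, y axis) for 6 gene lists in Control (blue) and MSUS (red) animals, with the mean and SD of 6 animals as bars. For oligodendrocyte markers the MSUS animals ran from -0.21 to 0.10 and the Control animals from -0.12 to 0.18.

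Markers of granule cells, pyramidal cells and adult neurogenesis gave no shift past the threshold. Dentate gyrus granule cell markers (15 genes) had a mean of -0.0064 ± 0.055 (adjusted p = 0.880) and a median of the other sign, 0.035. The mean was 0.015 ± 0.044 for CA1 pyramidal cell markers (11 genes, adjusted p = 0.675), 0.040 ± 0.030 for CA3 and CA2 markers (15 genes, adjusted p = 0.880) and 0.048 ± 0.029 for markers of adult neurogenesis (21 genes, adjusted p = 0.605). The granule cell gene C1ql2 differed by 0.18 ± 0.093 (SE) and the CA2 gene Amigo2 by 0.12 ± 0.067.

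Genes of the stress response showed no shift past the threshold at this resting time. The glucocorticoid and stress axis list had 20 of 29 genes on the higher side and a mean of 0.0031 ± 0.027 (adjusted p = 0.626). Immediate early genes, which neurons induce on activation, had a mean of 0.013 ± 0.11 (31 genes, adjusted p = 0.696). Their scores ran from -0.23 to 0.35 in Control animals and from -0.16 to 0.30 in MSUS animals. Without MSUS animal 7, which had the highest score of its group, the mean was -0.046 and passed camera (adjusted p = 0.0282), and without Control animal 4, the highest of its group, it was 0.085 and passed the other way (adjusted p = 0.0467). The estimated correlation of this list was 0.39, with which the adjusted p = 0.930 over all 12 animals, and it was not run without these animals. Genes of DNA methylation and chromatin had a mean of 0.0087 ± 0.035 (49 genes, adjusted p = 0.454), with the DNA glycosylase Mbd4 at 0.33 ± 0.11 (SE; 1 of its 2 features went the other way). The circadian clock list was lower (18 genes, 13 lower, mean -0.023 ± 0.042, camera adjusted p = 0.0304, and adjusted p = 0.494 with an estimated correlation). Without the outlying array its mean was -0.037 and did not pass (adjusted p = 0.0682), and with 1 animal left out it was -0.042 to -0.00020. Its mean was -0.019 with the slide as a block (adjusted p = 0.0800), -0.043 on the first slide (adjusted p = 0.149) and 0.00031 on the second (adjusted p = 0.134). Tef differed by -0.092 ± 0.048, Per2 by -0.12 ± 0.074, Dbp by 0.095 ± 0.067 and Nfil3 by 0.11 ± 0.081. Cholesterol synthesis (24 genes, mean 0.019 ± 0.026, adjusted p = 0.466) and the interferon response (26 of 29 genes on the higher side, mean 0.064 ± 0.062, adjusted p = 0.220) did not pass. The interferon mean was 0.038 without the outlying array. With 1 animal left out it was 0.033 to 0.11, past camera in 2 of 12 cases. With an estimated correlation over all 12 animals its adjusted p = 0.866. Camera compares a list with the other genes and placed 8 lists with a mean above 0 on the lower side, none past the threshold: immediate early genes, the stress axis, interneurons, neurotrophins, chromatin, astrocytes, CA1, and CA3 with CA2.

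Xist, the RNA that coats the inactive X chromosome in female cells (mm9 chromosome X, 100655711 to 100678572), was high in 11 of 12 animals and low in 1. Its brighter feature was 13.80 ± 0.33 in Control and 12.84 ± 2.60 in MSUS animals (SD, n = 6 each). It read 7.56 in MSUS animal 7 and between 13.22 and 14.14 in the others, and its dimmer feature read 4.92 against 9.97 to 11.17. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay between 5.67 and 6.62 in all 12 animals, near the random probes (5.35). The sex-linked list (5 genes) had a mean of -0.23 ± 0.23 (SE over animals, camera adjusted p = 0.0572, and adjusted p = 0.494 with an estimated correlation). On the first slide alone it was -0.31 (camera adjusted p = 0.00254) and on the second -0.22 (adjusted p = 0.474). With 1 animal left out it was -0.29 to -0.0047, past camera in 4 of 12 cases.

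**Figure D5:**
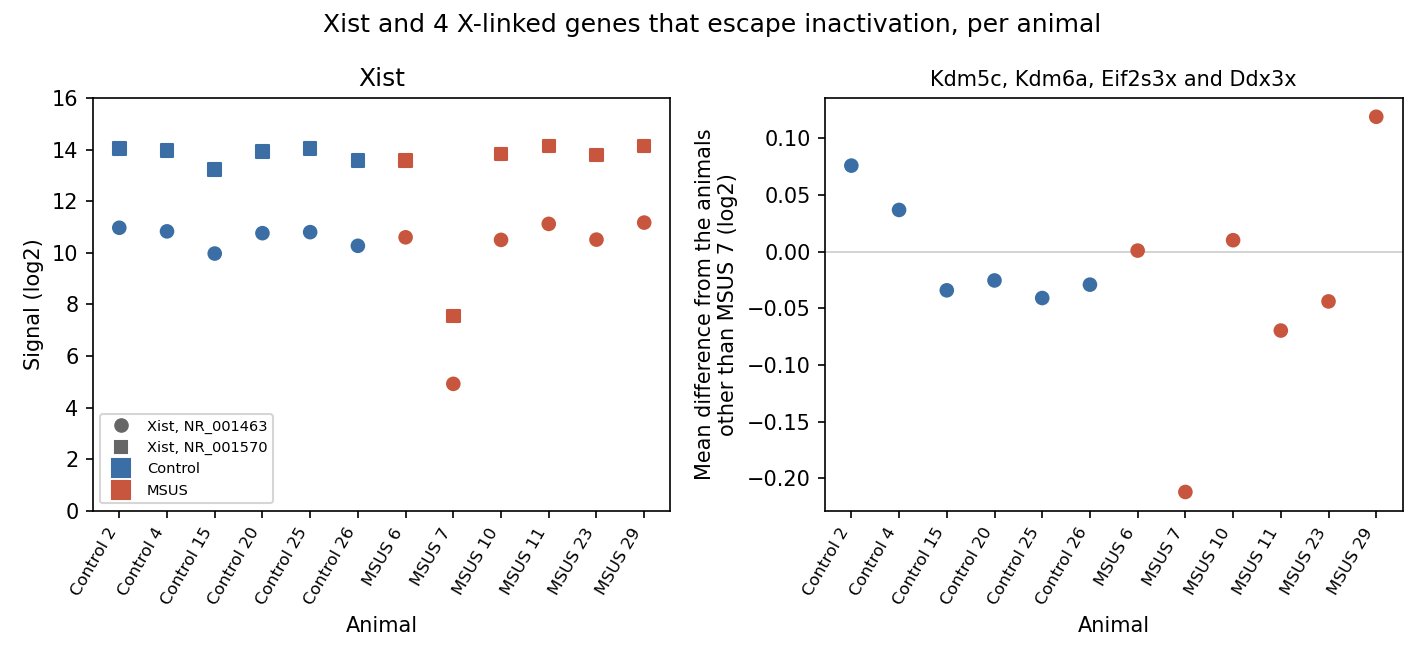
Left, log2 signal of the 2 Xist features (y axis) in each animal (x axis; Control blue, MSUS red), low in MSUS 7 alone. Right, mean of 4 X-linked genes in each animal as a log2 difference from the mean of the animals other than MSUS 7, with MSUS 7 at -0.21 and the others from -0.070 to 0.12.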

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

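Tests chosen only after the result was seen are the one of all glia, the one of a failed Xist feature, the one of Y-linked genes, the one of RNA of another animal, the splits without the outlying array, the exact permutation of list scores and the fits without the outlying array.

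In 17 of 274 groups of 6 animals (62 of list scores, 212 of named genes) 1 animal lay far from the rest by Dixon's test, where chance gives about 1 in 20, or 13.7. Each value is the animal's difference from the mean of the other 5 on the log2 scale. Among lists, these were glutamate receptors in MSUS 29 (0.20), presynaptic release in Control 4 (-0.078) and the sex-linked genes in Control 15 (-0.25) and MSUS 7 (-1.35). Among genes of synapses and signalling they were Bdnf in MSUS 11 (0.26), Camk2a in Control 15 (0.35), Gphn in MSUS 29 (-2.90), Gad2 in MSUS 10 (-0.30) and Sv2c in both Control 15 (-0.60) and MSUS 6 (-0.595). The others were Nlrp4g in MSUS 23 (-0.66), Rpl34 in Control 15 (0.15), Xbp1 in Control 2 (-0.12), Plk5 in MSUS 6 (-0.48), Draxin in MSUS 11 (0.40), Top2a in Control 15 (-0.255) and Xist in MSUS 7 (-6.34).

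Xist was low in MSUS animal 7 on both features and both arrays, with falls of at least 5.78 log2 units against the median of the other animals (-5.78 being a lower bound, since the dimmer feature read under the random probes), which argues against a failed feature or array. Activity of 2 X chromosomes would raise X-linked genes, and the median of 950 such features in this animal differed from the others by -0.0078, against it. A single X chromosome may account for the low Xist, since the mean of Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which escape inactivation, was lower than in each of the other 11 animals, by -0.14 against the lowest, mostly through Kdm6a (-0.43) and Eif2s3x (-0.27), while Kdm5c and Ddx3x lay within the range of the others. A male animal would also have 1 X and stays open: no Y-linked feature was more than 0.29 above the other animals, but none of the 27 was more than 8-fold above the random probes in any animal, so it is not known that they can detect their genes. Between the groups, the brighter Xist feature differed by -0.955 (interval -2.99 to 1.08, unadjusted p = 0.329 in limma). With MSUS 7 alone low, this cannot tell whether the fathers' stress has an effect on Xist.

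The second array of MSUS animal 29 had 541 features more than 1 log2 unit below its pair, where no other pair had more than 10 one way, and a median 0.25 above it. RNA of another of the 11 animals alone is argued against: over all features its correlation with its own pair (0.217) exceeded the highest with another animal (0.0834) by 0.133 ± 0.0059 (jackknife SE over chromosomes). A mixture and a fault in part of the array stay open, both untested. No biological explanation was tested.

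Oligodendrocyte markers differed by -0.093 and passed camera with the preset correlation alone. Chance could not be excluded, since 22 of 100 splits of the 12 animals, the real one included, gave a difference as large, with 0.164 as the highest of the others. A fall of all glia as large as -0.093 is argued against by the astrocyte list (0.0056 ± 0.029, SE over animals). A smaller fall of all glia stays open. The astrocyte SE is too wide to decide it, and the oligodendrocyte mean itself has an SE of 0.071. Tissue from next to the hippocampus stays open: with group means taken out, the oligodendrocyte score went with the thalamus and habenula score at r = 0.263 (permutation p = 0.404, adjusted p = 0.549 over 2 relations; rho = 0.112, permutation p = 0.733, adjusted p = 0.735), and r = -0.176 without the 2 animals farthest out, a range too wide to decide. The fathers' stress, which the design names, also stays open, untested beyond the comparison itself.

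For the comparison as a whole chance could not be excluded either. Of 100 splits of the 12 animals (of 462), the real one included, 77 gave at least the 1572 features at an unadjusted p under 0.05 of the real split, with 5921 as the highest of the others, several times the real count. Without the outlying array it was 93 of 100, with 1293 features in the real split and 6734 as the highest of the others, so that array alone does not make the large counts. Counts of that size may come from features that vary together across the animals, and no such structure was tested. At least the real 9 lists passed camera in 24 of 100 splits, again with the real one included, with 17 as the highest of the others.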

How the results depend on the processing

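Fits without the outlying array and the exact permutation of scores were chosen after seeing the data. limma called 0 features at an adjusted p under 0.05 in 26 of 27 other settings (a threshold of 0.1 included) and 1, Tex26, without the outlying array and with the slide as a block. Features at an unadjusted p under 0.05 fell from 1572 to 645 with the dimmest 50% left out and to 914 with 1 feature per gene, where fewer features are tested, and were 1280 to 1990 without 1 animal. The 16 fixed genes gave 0 calls in every setting run. Where 9 lists passed camera, 0 lists passed with an estimated correlation (also 0 without the outlying array), 0 with fry and 0 by exact permutation of scores (smallest adjusted p = 0.470), 5 passed with array weights, 5 with animals on both slides (4 of the 9 and sex-linked genes), 7 on the first slide alone (5 of the 9, microglia markers and sex-linked genes) and 1, oligodendrocyte markers, on the second; the cause was not tested. Without 1 animal 1 to 13 lists passed: 1 without Control 2, 2 without MSUS 10, 4 without Control 20 and 5 without MSUS 6. On the second slide the GABA (0.0034), circadian clock (0.00031) and choroid plexus (0.0023) means changed sign. The median difference over all features was 0.044 there, against 0.019 over all arrays, and these means lay below it. Their unadjusted camera p on that slide was 0.0458, 0.0302 and 0.0128. The second slide holds the outlying array, which there stands alone for MSUS animal 29. Over both slides without that array the 3 means were -0.040, -0.037 and -0.091. The sign changes on the second slide therefore cannot be told apart from an effect of that array. Without MSUS 7 the immediate early gene mean changed sign (-0.046), and without Control 4 it was 0.085 and passed. The oligodendrocyte call held without each of the 12 animals (-0.13 to -0.060). The consensus correlation of 0.543 between arrays of one animal became 0.692 without the outlying array, 0.655 with quantile normalization repeated and 0.657 with each array centred. Of 929 other list values 78 had the other sign with no call on either side, as had 39 of 415 values of fixed genes and 8 of 1914 of list members. Of the features, 61.7% lie more than 2-fold above the random probes; dimmer ones have little signal to show a difference.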

Other observations

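The transcripts below were chosen after their values were seen, by a rule set on the same data: an animal more than 2 log2 units from the median of the other 11, more than 1.5 on each of its arrays and more than 1 beyond the nearest other animal. It took 27 features in 7 animals, 24 of them higher, and by its making it can take no feature shared by a group.

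Control animal 20 carried transcripts of pituitary hormones. Prl, which encodes prolactin (mm9 chromosome 13, 27149445 to 27157046), read 13.06 in this animal and 5.56 to 6.84 in the other 11, at least 7.03 above their median, which is near the random probes (5.35). Gh, growth hormone, read 10.36 against 5.39 to 5.54, and Cga, the shared subunit of the glycoprotein hormones, read 7.88 against 5.44 to 5.74. The rule also took Eif3a, a translation initiation factor, there (9.01 against at most 7.38). Both arrays showed each of them. Pomc, the precursor of corticotropin, was also highest there (7.18 against at most 6.26), while Fshb (5.58), Lhb (5.54) and the pituitary transcription factor Pou1f1 (5.56) were near the random probes, and Tshb (7.49 against at most 7.52) and Ghrhr (6.57 against at most 6.65) were not highest there.

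Control animal 25 had 10 features of the immunoglobulin kappa locus (mm9 chromosome 6, 68071047 to 70676960) above the median of the other animals by 2.81 to 4.25 log2 units, and the highest of the other animals read up to 10.70 at them. Jchain, which joins secreted immunoglobulin, was highest in the same animal (7.43 against at most 6.59), while Ighm, the heavy chain of IgM, was barely so (9.29 against at most 9.28) and Mzb1, of antibody-secreting cells, was not (5.74 against at most 5.77). The chemokine Ccl2 was highest there as well (8.77 against at most 6.59). One feature of the growth factor Igf2 (8.96 against at most 7.71) was taken too. Its brighter feature was not taken and barely stood out there (11.9 against at most 11.72). The rule also took AK007918, a transcript without a gene name (9.13 against at most 7.33). AK007918 (mm9 chromosome 12, 114525497 to 114667344) overlaps the span of the Ighm feature (114656768 to 116831787). MSUS animal 6 had the mast cell protease genes Cpa3 (7.73 against at most 6.38), Tpsb2 (8.64 against at most 7.52) and Mcpt4 (8.02 against at most 6.81), and Cma1, a further mast cell protease that the rule did not take, was 7.63 against at most 6.89. Other mast cell genes were not highest there: Tpsab1 (5.61 against at most 5.62), Hdc (8.81 against at most 9.01) and Kit (14.04 against at most 14.21). Tpsab1 was near the random probes in every animal. Kit, also on the CA3 and CA2 marker list, read at least 13.83 in every animal. Neither can therefore speak for or against mast cell transcripts. MSUS animal 7, the animal low in Xist, had Mael, a germline gene that represses transposons, at 8.33 against at most 6.83. Single features taken in other animals include Tmem87a in Control 2 (higher by 2.13) and Iqcm in MSUS 23 (higher by 2.31).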
